A study of Mus musculus with 7 samples.

How the data were processed

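Bulk RNA sequencing was run on the Illumina HiSeq platform in fibroblasts sorted from mouse hearts of pooled male and female animals. In both mouse lines a tamoxifen-activated recombinase, MerCreMer, was expressed from the gene of a fibroblast protein, either periostin (Postn) or the transcription factor Tcf21, and switched on a green fluorescent reporter in the cells that had expressed that gene. Reporter-positive cells were collected by fluorescence-activated sorting. The 7 libraries fell into 3 groups, Postn-traced cells at postnatal day 7 (Postn P7, n = 2), Tcf21-traced cells at day 7 (Tcf21 P7, n = 2) and Tcf21-traced cells at day 30 (Tcf21 P30, n = 3).

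The authors deposited a table of raw counts per gene symbol, with each replicate in its own column and no normalization. Per the labels, the aligner was STAR and the genome build GRCm38. The STAR version, the counting program, the annotation release and the strand setting were not given in the sources used here. The values were whole numbers, with 15207835 to 18519528 counts per library. Of the 54735 symbols, 21563 had no count in any library. Gene coordinates and types were taken from the GENCODE annotation of GRCm38, which held 54075 of the symbols. Because counts were made per symbol, reads shared between paralogs or between overlapping genes on opposite strands could not be assigned anew.

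Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 17636 genes. Libraries were scaled by the trimmed mean of M values (TMM), and all 7 libraries were fitted together with a mean per group by the robust quasi-likelihood method. The 3 group differences were tested with the quasi-likelihood F-test, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are given as normalised CPM, counts scaled to a common library total, with the SD over the libraries of a group. Fold changes are on the log2 scale. Their standard error was derived from the F-test, as the absolute change divided by the square root of F. It therefore restates the test, and it is approximate where a group has few counts. A gene is called higher or lower only where its adjusted p passed the threshold. The p-values measure the spread between these libraries. The labels do not say whether the libraries came from separate animals, litters or sorts, so part of that spread may be technical. The labels give no batch. Replicate numbers were not used to pair libraries, because the labels do not say that a number marks a shared litter, day or batch. Deviations of equally numbered libraries from their group means correlated across genes with coefficients of 0.04 to 0.31. The coefficients were 0.29 and 0.31 between Postn P7 and Tcf21 P30. In a group of 2 libraries the deviations mirror each other, so these coefficients do not count separately. Replicate 1 of both groups held more endothelial transcripts than the other libraries of its group. Something shared by equal numbers was not excluded there.

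Before the data were examined, 32 gene lists with 592 members were written down, covering markers of fibroblasts and of the other cell types a heart holds, extracellular matrix, cell division, imprinted growth genes, signalling, immune genes, metabolism and the response to cell dissociation. Lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and again with a correlation estimated from the data, and with fry. List p-values were adjusted over the 32 lists. The genes named in each comparison were chosen by a rule fixed at the same time. They were the lineage genes, the 10 largest increases and the 10 largest decreases among called genes with at least 10 CPM in the higher group and no overlap between the libraries compared, without predicted gene models, and up to 4 of the largest changes among the called members of each list. Where no member passed, the most expressed member was given. Genes named outside this rule are stated as such.

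The comparisons of Postn P7 and of Tcf21 P30 with Tcf21 P7 share the same control libraries. The overlap of their calls was set against the number expected for independent lists, and the covariance and correlation of their fold changes against 50 simulated data sets in which nothing changed and the same libraries were shared. The comparisons were also made with 1 Tcf21 P7 library each as the control, where a lone library is assumed to vary like the other groups.

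The procedure was tested on simulated data with known changes. In the comparison of lineages, 26 of 66 genes changed 2-fold and 42 of 64 genes changed 4-fold were called, against 3 of 65 genes changed 1.5-fold, and 13 of 16978 unchanged genes were called. In the comparison of ages, 29 of 66 genes changed 2-fold and 49 of 63 changed 4-fold were called, and 7 of 16948 unchanged genes. In that of Postn P7 with Tcf21 P30, 8 of 16932 unchanged genes were called. In each comparison, with a single simulated data set each, unchanged genes made up more than a share of 0.05 of all calls. No changed gene was called in the wrong direction. In the simulated lists, camera with the preset correlation called 2 of 31 unchanged lists in the comparison of lineages. It called 3 of 31 in the comparison of ages. Camera with an estimated correlation called none. The simulated genes varied alike in all groups and independently of each other. The real groups differed in their spread and genes of a list were correlated, so these rates need not hold for the real calls.

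The alternatives tried were other scalings (size factors as in DESeq2, upper-quartile factors, library size alone), other filters, a non-robust fit, a block for replicate number, a minimum fold of 2, a test against a 2-fold change, fits of only the groups compared, DESeq2 1.42.0, limma-voom and leaving out each library in turn. Further alternatives were chosen after the data were seen. They summed the Tcf21 P7 libraries into 1, kept only protein-coding genes, left out both libraries richest in endothelial transcripts (Postn P7 replicate 1 and Tcf21 P30 replicate 1), or gave each of 2 comparisons its own Tcf21 P7 library. No library and no gene was left out of the reported fit beyond the filter on low counts. Raw reads were not used here.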

Results

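Gene expression was measured in cardiac fibroblasts that had been marked genetically and sorted from mouse hearts during the weeks after birth. Postn encodes periostin, a secreted matricellular protein of activated and developing fibroblasts, and Tcf21 encodes a transcription factor of resident cardiac fibroblasts. The series was made to describe subpopulations of fibroblasts during postnatal growth of the heart. Postn P7 comprised 2 libraries, with 17481102 and 15207835 counts. Tcf21 P7 comprised 2 libraries, with 18057876 and 17765189 counts. Tcf21 P30 comprised 3, with 15959931, 16371239 and 18519528 counts. In a principal component analysis the first component held 51.8% of the variance and separated the ages, and the second held 21% and separated the lineages at P7. Replicate libraries differed by more than sampling noise in every group. The ratio of chi-squared to its degrees of freedom was 3.55 between the Tcf21 P7 libraries, which lay closest together. It was 20.2 between the Postn P7 libraries and 10.8 to 42 between the Tcf21 P30 libraries.

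The genes that drove the recombinase were examined first, to relate the labels to the counts. Postn (chromosome 3, 54361109 to 54391037 in GRCm38, protein coding) was measured at 3350 ± 495 CPM (SD, n = 2) in Postn P7 and at 4400 ± 206 CPM (SD, n = 2) in Tcf21 P7. The difference of -0.40 ± 0.15 on the log2 scale was not called (adjusted p = 0.11). At P30 it had fallen to 828 ± 75.9 CPM (SD, n = 3), and the decrease from Tcf21 P7 was -2.41 ± 0.13 (adjusted p = 3.6e-05). Tcf21 (chromosome 10, 22817281 to 22820174, protein coding) was measured at 385 ± 60.2, 351 ± 4.58 and 338 ± 61.6 CPM in Postn P7, Tcf21 P7 and Tcf21 P30. It was called in none of the 3 comparisons. The Postn-traced and Tcf21-traced cells of P7 were thus not told apart by the current level of either driver gene. Esr1, the oestrogen receptor gene, did separate them, at 3.20 ± 0.633 CPM in Postn P7, 173 ± 0.199 CPM in Tcf21 P7 and 198 ± 32.9 CPM in Tcf21 P30. MerCreMer contains ligand-binding sequence of the mouse oestrogen receptor, and counts per symbol do not separate transcripts of the recombinase from those of the Esr1 gene (chromosome 10, 4611593 to 5005614). The animals were pooled males and females, and the sex-linked transcripts differed between groups. The Y-linked Ddx3y stood at 70.3 and 97.1 CPM in Postn P7, 32.8 and 38.5 CPM in Tcf21 P7 and 13 to 36 CPM in Tcf21 P30. Xist stood at 69.4 and 29.1, 27.7 and 30.9, and 83.8 to 119 CPM. The proportion of each sex per library was not given, and an effect of sex was not separated from lineage or age.

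**Figure D1:**
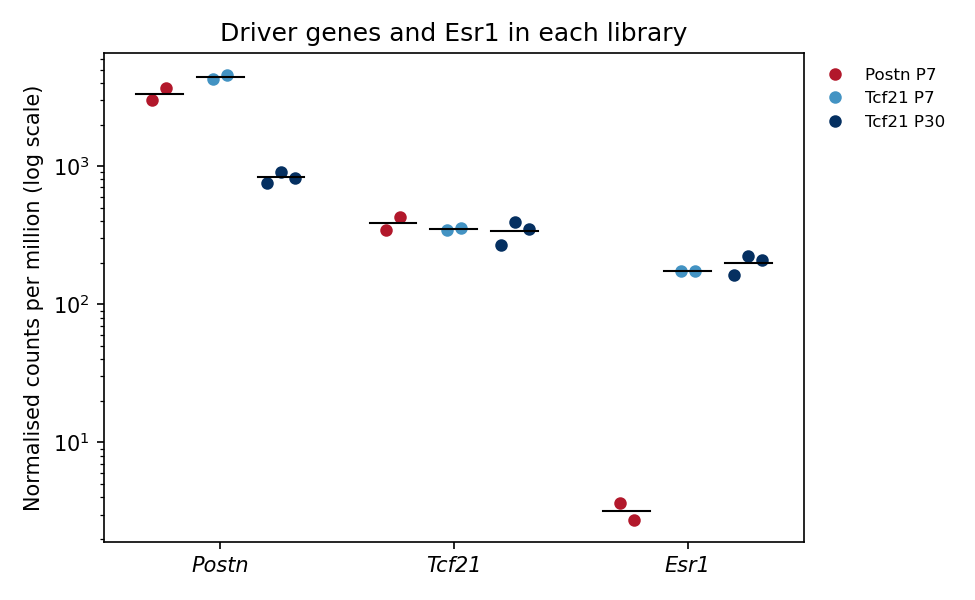
Normalised CPM (log axis) of Postn, Tcf21 and Esr1 in each library, with a line at the mean of each group. Postn lay at 756 to 907 CPM in the Tcf21 P30 libraries and at 3000 CPM or above in the P7 libraries, and Esr1 lay at 2.75 and 3.65 CPM in the Postn P7 libraries and at 162 CPM or above in the Tcf21 libraries.

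The comparison of Postn P7 with Tcf21 P7 asked how fibroblasts traced by periostin expression differed from the broader fibroblast lineage at the same age. Of 15 markers of universal and adventitial fibroblasts 8 were lower in Postn P7, and 1 was with the Tcf21 P7 libraries summed. Pi16, a peptidase inhibitor gene of adventitial fibroblasts (chromosome 17, 29317680 to 29330593), was measured at 236 ± 7.71 CPM (SD, n = 2) against 714 ± 47.4 CPM (SD, n = 2), a change of -1.59 ± 0.12 on the log2 scale. Dpp4, a surface peptidase of fibroblast progenitors, changed by -1.21 ± 0.19 and Clec3b, which encodes tetranectin, by -1.46 ± 0.18. Transcripts of macrophages were lower as well, among them C1qa at 23.7 ± 0.0691 against 104 ± 3.42 CPM. The mitotic genes Cenpe and Cenpf were higher, by 1.49 ± 0.26 and 1.40 ± 0.21. Enpep, an aminopeptidase of pericytes and other mesenchymal cells (chromosome 3, 129269175 to 129332720), was 118 ± 4.65 CPM in Postn P7 and 22.2 ± 1.13 CPM in Tcf21 P7 (2.41 ± 0.10, adjusted p = 7.6e-05).

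Of the 17636 genes tested, 2118 (12%) were called between the lineages, 1149 higher and 969 lower in Postn P7. Before adjustment 5362 genes had a p under 0.05. With library size alone as the scaling, which moved the median of all genes by 0.113 on the log2 scale, 1741 genes were higher and 472 lower. With upper-quartile factors 1187 were higher and 647 lower. The count rested on both Tcf21 P7 libraries. Without replicate 1 or 2 of that group 118 or 111 genes were called, and with its libraries summed 123 were called. Without replicate 1 or 2 of Postn P7 the number was 1106 or 507, and it was 3750 without both endothelial-rich libraries. These were Tcf21 P30 replicate 1, with 5050 CPM of endothelial transcripts, and Postn P7 replicate 1, with 2260 CPM against 1420 to 1710 CPM in the others, and leaving them out left Postn P7 with 1 library. With the Tcf21 P7 libraries summed, 13 of the 86 named genes called here kept their call (Tpm3-rs7, Dnm3os, Kcnq1ot1, Enpep, Firre, Esr1, Folr2, Alox5, C1qa, Dlk1, Pi16, Adgre1 and Sema3b). With these libraries summed, the members of the 32 lists still called were 4 macrophage genes and 1 gene each of the universal fibroblast, imprinted and neurotrophic lists. Of the genes named below by the fixed rule, Fosb, Meg3, Lamc1, Col14a1, Serpinh1, Cald1, Fzd2, Apoe and Ebf1 were not called with upper-quartile factors. In the reported fit 32 genes passed a test against a 2-fold change.

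The largest increases in Postn P7 included several long non-coding RNAs. Dnm3os, which lies antisense to Dnm3 and hosts microRNAs (chromosome 1, 162217623 to 162225550), rose from 6.41 ± 0.174 CPM in Tcf21 P7 to 67.7 ± 22.6 CPM in Postn P7 (3.40 ± 0.24). Kcnq1ot1, the imprinted antisense RNA of Kcnq1 (chromosome 7, 143203458 to 143296549), was higher by 2.90 ± 0.28. Firre, a nuclear RNA of chromosome X, was higher by 2.27 ± 0.14, the smooth muscle RNA Carmn by 2.30 ± 0.42 and the imprinted Meg3 by 2.04 ± 0.48. The nuclear RNAs Malat1 (1.87 ± 0.12) and Neat1 (1.60 ± 0.15), named after their values were seen, were higher in Postn P7 too, as were the provisional gene models described below. The increases of Kcnq1ot1, Firre and Meg3 were not separated from such a shared rise. Counts of antisense RNAs depend on a strand setting that is unknown here. Tpm3-rs7 (chromosome 14, 113314608 to 113316754) had the largest increase (3.59 ± 0.35), but it is a close relative of Tpm3, whose reads it may share. The remaining named increases were Fosb (2.84 ± 0.61), an immediate early transcription factor, Lgals4 (2.52 ± 0.31), a galectin gene, and Ifih1 (2.49 ± 0.57), a sensor of viral RNA. Fosb, Ifih1 and Meg3 were not called with limma-voom. Besides Esr1 (-5.74 ± 0.21, adjusted p = 7.3e-05), the largest decreases were Folr2 (-2.43 ± 0.32), Alox5 (-2.32 ± 0.23), Cbr2 (-2.31 ± 0.34), Clec4n (-2.29 ± 0.49), C1qa (-2.13 ± 0.18), Ms4a7 (-2.08 ± 0.35) and C1qb (-2.04 ± 0.29), most of which are known from macrophages. They were joined by the growth regulator Dlk1 (-1.99 ± 0.21) and the oxidase maturation factor Duoxa1 (-2.00 ± 0.28).

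Among the fibroblast lists, 8 of the 15 universal and adventitial fibroblast genes were lower and none higher in Postn P7, and 10 were lower when adjusted over the list alone (camera adjusted p = 3.6e-09; adjusted p = 0.54 with an estimated correlation). The fibroblast identity list was lower by camera (adjusted p = 0.0027), with a median of -0.24, although Lamc1 was its sole called member of 20 (a call lost with each of the other 3 scalings) and none passed when adjusted over the list alone. Of 16 elastic fibre genes, 4 were lower, and 7 when adjusted over the list alone (adjusted p = 3.4e-05), with Efemp1 at -1.37 ± 0.22 and Mfap5, a microfibril gene, at -0.67 ± 0.15. Of 23 collagen genes, Col5a3 (-1.12 ± 0.13), Col6a2 (-0.64 ± 0.12) and Col14a1 (-0.54 ± 0.13) were among 4 that were lower, whereas the basement membrane gene Col4a5 was higher (0.66 ± 0.13; list adjusted p = 0.0031). Adjusted over the list alone, 8 were lower and 1 higher. Of 23 genes for collagen processing, 3 were lower (adjusted p = 0.0059), including Loxl4 and the collagen chaperone Serpinh1 (-0.51 ± 0.11). Of 15 valve and tendon-like genes Comp (-1.18 ± 0.25) and Prelp (-0.71 ± 0.13) were lower (adjusted p = 0.045). Without Postn P7 replicate 1 the fibroblast identity list had an adjusted p of 0.05, which missed the threshold before rounding, and the collagen processing list 0.1. The valve list had 0.14 without Postn P7 replicate 2. The number of lower genes depended on the scaling. It was 2 for elastic fibres with each of the other 3 scalings, and with upper-quartile factors 5 for universal fibroblasts, 2 for collagens and 1 for collagen processing. With library size alone 2 collagen processing genes were lower and 2 higher. With the Tcf21 P7 libraries summed 1 universal fibroblast gene was lower and no gene of these 3 matrix lists. With estimated correlations the adjusted p of the other 5 lists was 0.7 for fibroblast identity, 0.6 for elastic fibres, 0.7 for collagens, 0.76 for collagen processing and 0.58 for the valve list.

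Matricellular genes moved both ways, with Wisp1 (1.42 ± 0.22) and Thbs4 (0.99 ± 0.18) higher, 4 of 19 lower (1 with library size alone as the scaling, 2 with the other scalings) and no call for the list (adjusted p = 0.21). Among proteoglycans 3 of 20 were lower (2 higher and 1 lower with library size alone), including Prelp, and the median of the list was 0.02 while its mean (-0.04) and test pointed down. Among matrix proteases and their inhibitors Adamtsl2 (-1.11 ± 0.15) and Adamts15 (-1.05 ± 0.16) were among 3 that were lower, while Mmp16 was higher (0.78 ± 0.19; 2 higher and 2 lower with library size alone). Neither list was called (adjusted p = 0.47 and 0.067). Of the 17 smooth muscle and myofibroblast genes, Synpo2 (0.94 ± 0.25) and Cald1 (0.41 ± 0.11) were higher, and the list was not called (adjusted p = 0.22).

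Some mitosis genes were higher in Postn P7. Of 24 mitosis genes 6 were higher and none lower, and 8 were higher when adjusted over the list alone (adjusted p = 1.8e-05; adjusted p = 0.58 with an estimated correlation). With the Tcf21 P7 libraries summed, 0 were higher. They included the kinetochore genes Cenpe, at 25.4 ± 1.83 against 9.01 ± 1.32 CPM, and Cenpf, the spindle motor Kif11 (0.97 ± 0.18) and Hmmr (1.25 ± 0.24). None of 24 DNA replication genes was called, with 0 also when adjusted over the list alone, while 1 was higher with size factors as in DESeq2. The most expressed of them, Mcm6, differed by 0.11 ± 0.11 (list adjusted p = 0.65). The imprinted growth genes were lower as a list (adjusted p = 0.0031; adjusted p = 0.54 with an estimated correlation), with Dlk1 and H19 (-1.49 ± 0.33) lower and Meg3 higher among 15, and with 5 lower and 1 higher when adjusted over the list alone. Without Postn P7 replicate 1 the imprinted list had an adjusted p of 0.05, which missed the threshold before rounding. H19 lost its call when any of the P7 libraries was left out, with adjusted p of 0.15 and 0.16 without Postn P7 replicate 1 and 2 and 0.2 and 0.21 without Tcf21 P7 replicate 1 and 2.

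The series was concerned with neuronal maturation as well as muscle, and genes of secreted neural signals were therefore of interest. Of 25 neurotrophic and axon guidance ligands tested, Bdnf, a neurotrophin gene (chromosome 2, 109674700 to 109727007), was higher in Postn P7, at 3.47 ± 0.473 CPM against 0.545 ± 0.208 CPM (2.66 ± 0.41). Sema3b (-1.13 ± 0.13) and Ntn4 (-0.79 ± 0.13) were lower. The list was not called (adjusted p = 0.38), and its mean was 0.05 while its median (-0.07; 0.04 with library size alone as the scaling) and test pointed down. Bdnf lost its call without Tcf21 P7 replicate 1 (adjusted p = 0.1) or 2 (adjusted p = 0.064). Of 25 secreted growth factors 3 were higher, among them Fgf7 (1.47 ± 0.27), and 3 were lower, Fgf16 (-1.10 ± 0.28), Fgf18 (-1.03 ± 0.21) and Bmp6 (-0.77 ± 0.10). The list was not called (adjusted p = 0.86), with a median of 0.22 and a test that pointed down. Fgf16 was not called with library size alone as the scaling. Of 22 TGF-beta and BMP signalling genes, Id4 (0.85 ± 0.13) and the receptor gene Bmpr1a (0.51 ± 0.10) were among 3 that were higher, and Smad3 (-0.70 ± 0.14) was among 2 that were lower (list adjusted p = 0.61). Of 25 Wnt genes, Sfrp4 (1.51 ± 0.23) and Rspo3 (1.97 ± 0.53) were higher and Fzd2 was lower, a call lost with upper-quartile factors and with library size alone. The Wnt list was not called (adjusted p = 0.65), with a median of -0.13 (0.03 with the Tcf21 P7 libraries summed) while its mean (0.26) and test pointed up. Of 15 IGF system genes, Stc2 (-0.86 ± 0.16) and Igfbp6 (-0.73 ± 0.14) were lower (list adjusted p = 0.2), and with library size alone 2 were higher as well.

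No interferon response or antigen presentation gene of 23 was called, and the most expressed of them, H2-D1, differed by -0.27 ± 0.42 (list adjusted p = 0.77). C1s1 was the sole called gene of 11 complement genes (0.78 ± 0.16; list adjusted p = 0.65), and Tnfsf13b (2.24 ± 0.53) and Cxcl1 (1.38 ± 0.32) were the called chemokine and cytokine genes of 19 (list adjusted p = 0.053). Of 16 lipid genes, Cebpa (-1.18 ± 0.20), Scd1 (-0.73 ± 0.12) and Apoe (-0.56 ± 0.14) were lower and Ebf1 was higher (0.42 ± 0.11). The list was lower (adjusted p = 0.035; adjusted p = 0.54 with an estimated correlation). Its adjusted p was 0.096 without Postn P7 replicate 1. Of 17 retinoid and glucocorticoid responsive genes, Aldh1a3 (-0.82 ± 0.17) was lower and Errfi1 (0.53 ± 0.13) higher (list adjusted p = 0.38). Of 22 immediate early and dissociation stress genes, Fosb and the heat shock gene Hspa1a (1.10 ± 0.16) were higher (list adjusted p = 0.0031; adjusted p = 0.7 with an estimated correlation), and without Postn P7 replicate 2 the list's adjusted p was 0.37.

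Some markers of other cell types were called between the lineages. Of 17 macrophage and myeloid genes 12 were lower in Postn P7, and 14 when adjusted over the list alone (adjusted p = 2.9e-17; adjusted p = 0.54 with an estimated correlation). With the Tcf21 P7 libraries summed, 4 were lower. Summed over the list, macrophage transcripts amounted to 420 and 576 CPM in the Postn P7 libraries, 1380 CPM in each Tcf21 P7 library and 492 to 724 CPM in the Tcf21 P30 libraries. Pericyte genes were higher as a list (adjusted p = 0.0065; adjusted p = 0.7 with an estimated correlation), with Pdgfrb called (0.61 ± 0.09) among 12. They summed to 1890 and 2540 CPM in Postn P7 against 1220 and 1290 CPM in Tcf21 P7. Of 10 Schwann cell and glia genes tested, the neuregulin receptor gene Erbb3 (2.36 ± 0.60) was among 2 that were higher (list adjusted p = 0.035; adjusted p = 0.7 with an estimated correlation). Erythroid genes were lower as a list with no called member of 8 (adjusted p = 0.045; adjusted p = 0.76 with an estimated correlation). Without Postn P7 replicate 1 the pericyte list had an adjusted p of 0.07. The Schwann cell list had 0.078 and the erythroid list 0.44 without Postn P7 replicate 2, and without Tcf21 P7 replicate 1 the Schwann cell list had 0.059. No called member was found among 14 endothelial, 20 cardiomyocyte or 9 lymphocyte genes (list adjusted p = 0.86, 0.066 and 0.47). Aldh1a2 (-0.69 ± 0.12) was the sole called gene of 11 epicardial and mesothelial genes (list adjusted p = 0.35). The test of that list pointed down while its median was 0.58.

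**Figure D2:**
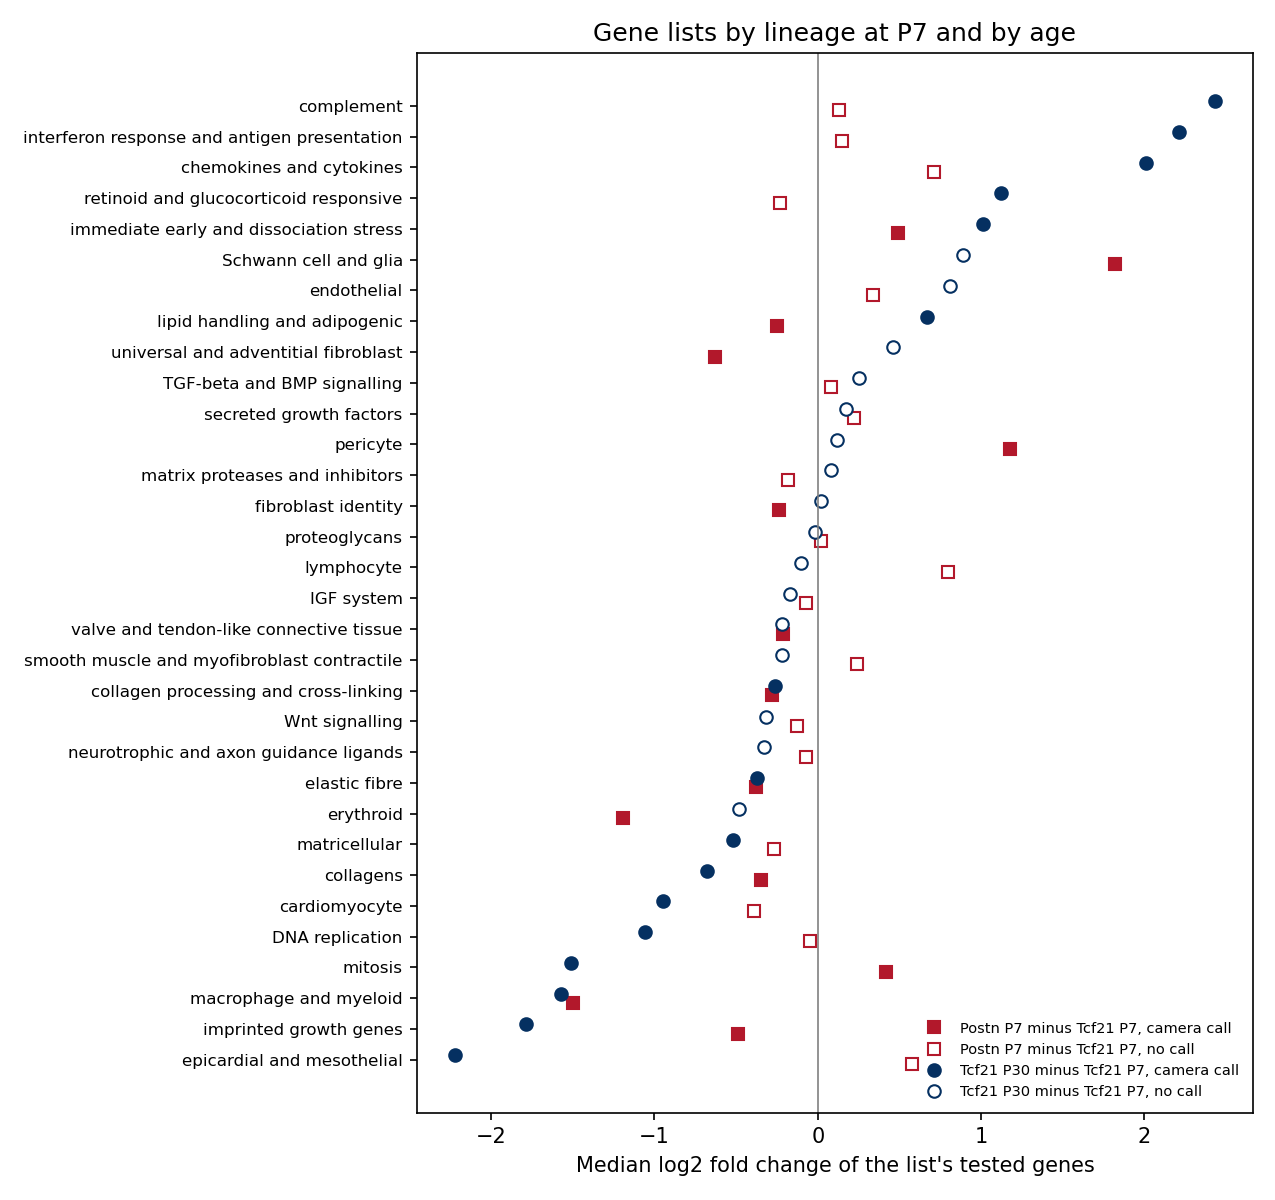
Median log2 fold change of the tested genes of each of the 32 lists, for Postn P7 minus Tcf21 P7 (squares) and Tcf21 P30 minus Tcf21 P7 (circles), filled where camera called the list with the preset correlation. Macrophage genes had medians of -1.50 and -1.57 in the comparisons of lineage and age, while the mitosis list had medians of 0.42 and -1.51.

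**Figure D3:**
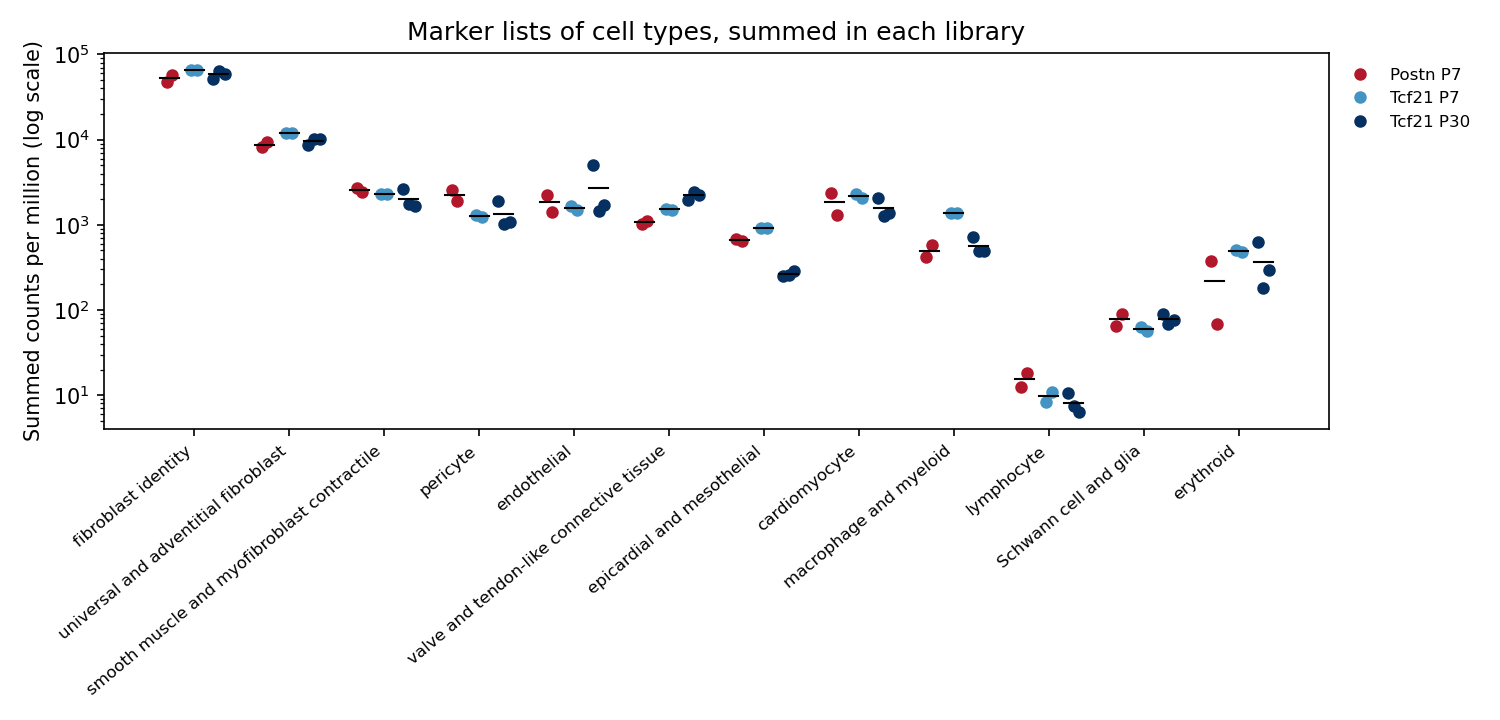
Normalised CPM (log axis) summed over the marker list of each cell type, with a point per library and a line at the mean of each group. Macrophage markers summed to 1380 CPM in each Tcf21 P7 library and to 420 to 724 CPM in the others, and endothelial markers to 5050 CPM in Tcf21 P30 replicate 1 and to 1420 to 2260 CPM in the others.

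The comparison of Tcf21 P30 with Tcf21 P7 asked how the fibroblast lineage changed between the first week and the first month of life. Most cell division and imprinted growth genes fell, most interferon, complement and chemokine genes rose, and most macrophage genes fell. With an estimated correlation only the imprinted list was called. The imprinted H19 (chromosome 7, 142575529 to 142578143) fell from 142 ± 0.461 CPM (SD, n = 2) to 1.11 ± 0.795 CPM (SD, n = 3), a change of -7.01 ± 0.38. Dlk1 (chromosome 12, 109452823 to 109463336) fell from 73.8 ± 3.78 to 0.605 ± 0.197 CPM (-6.92 ± 0.24). The complement gene C3 (chromosome 17, 57203970 to 57228136) rose from 13.4 ± 6.17 to 957 ± 113 CPM (6.16 ± 0.69), and the chemokine gene Cxcl14 (chromosome 13, 56288643 to 56296551) from 0.344 ± 0.166 to 52.4 ± 10.4 CPM (7.22 ± 0.54). The fibrillar collagen gene Col1a1 fell from 10500 ± 241 CPM to 5280 ± 649 CPM.

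Of the genes tested, 5604 (31.8%) were called with age, 2952 higher and 2652 lower at P30. Without replicate 1 or 2 of Tcf21 P7 2442 or 2418 genes were called, and with its libraries summed 2463 were called, with 100 of the 119 named genes called here among them. With these libraries summed 3 cardiomyocyte and 9 collagen genes fell and 8 chemokine genes rose. Elastic fibre genes rose in 1 and fell in 5 cases, proteoglycans in 2 and 4, fibroblast identity genes in 3 and 4, valve genes in 4 and 4 and TGF-beta genes in 4 and 1, and collagen processing genes fell in 3.

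The other large increases were in Inmt, an N-methyltransferase gene (7.98 ± 0.74), the matrix protease Mmp3 (6.87 ± 0.29), the non-coding Lncpint (6.11 ± 0.40), Hsd11b1 (5.84 ± 0.33), whose enzyme activates glucocorticoids, the complement gene C7 (5.40 ± 0.34) and Gdap10 (5.25 ± 0.42). Gsta3 (5.67 ± 0.29) and Ifi205 (5.43 ± 0.45) belong to families of similar genes, and their counts are uncertain for that reason. The largest decrease was that of Tnni1, the slow skeletal troponin I gene expressed in the immature heart (chromosome 1, 135779434 to 135810989), from 36.1 ± 2.12 to 0.185 ± 0.171 CPM (-7.58 ± 0.43). Cthrc1, a secreted regulator of collagen, changed by -5.49 ± 0.16 on the log2 scale, Plppr5 by -5.01 ± 0.25, Cpa1 by -4.94 ± 0.25, Adamts17 by -4.64 ± 0.32 and Megf6 by -4.48 ± 0.13. The collagen gene Col24a1 fell from 20.9 ± 2.37 to 0.742 ± 0.0996 CPM. Zim1 fell as well (-5.02 ± 0.51), but it overlaps Peg3 and the origin of its reads is uncertain.

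Of 24 mitosis genes 23 fell, and all 24 when adjusted over the list alone (adjusted p = 1.5e-22; adjusted p = 0.1 with an estimated correlation). Cdk1 was measured at 50.8 ± 3.74 CPM at P7 and 8.14 ± 1.44 CPM at P30 (-2.64 ± 0.18). Birc5 stood at -2.23 ± 0.21 and Bub1b at -2.04 ± 0.14. Of 24 DNA replication genes 21 fell, and 22 when adjusted over the list alone (adjusted p = 5.3e-14; adjusted p = 0.16 with an estimated correlation), among them Uhrf1 (-2.44 ± 0.19) and the helicase gene Mcm2 (-2.02 ± 0.17). Of 15 imprinted growth genes 13 fell (adjusted p = 3.3e-22), including Igf2 (-4.35 ± 0.49), and this was the sole list of the 3 comparisons called with an estimated correlation (adjusted p = 0.027). Adjusted over the list alone, 13 of its members fell and 2 rose. In the IGF system 7 of 15 genes fell and 4 rose (adjusted p = 0.2), with the RNA-binding genes Igf2bp1 (-6.04 ± 0.58) and Igf2bp3 (-2.78 ± 0.17) among those that fell.

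The extracellular matrix lists were remodelled in both directions. Of 23 collagen genes 14 fell and 3 rose (adjusted p = 0.00014; adjusted p = 0.39 with an estimated correlation), with Col11a1 at -3.59 ± 0.39 and the short-chain collagen Col8a1 at 2.45 ± 0.16. Of 23 collagen processing genes 6 fell and 1 rose (adjusted p = 0.0034; adjusted p = 0.75 with an estimated correlation), including the prolyl hydroxylase gene P4ha3 (-3.02 ± 0.22) and the cross-linking enzyme gene Lox (-1.41 ± 0.09). Of 16 elastic fibre genes 8 fell and 5 rose (adjusted p = 0.00087; adjusted p = 0.42 with an estimated correlation). Fbn2 fell from 364 ± 0.269 to 35.5 ± 6.1 CPM and elastin, Eln, from 4310 ± 43.3 to 1720 ± 92.8 CPM, while Efemp1 rose (2.03 ± 0.20). Of 19 matricellular genes 9 fell and 7 rose (adjusted p = 0.00027; adjusted p = 0.3 with an estimated correlation), with tenascin C, Tnc, at -3.59 ± 0.27 and Wisp1 at -2.85 ± 0.22. Among 20 proteoglycans 6 rose, such as Omd (2.70 ± 0.17), and 7 fell. Among 23 proteases and inhibitors 7 rose and 10 fell, such as Adam12 (-3.27 ± 0.17). Neither list was called (adjusted p = 0.48 and 0.71), and the protease list had a median of 0.08 and a mean of 0.22 while its test pointed down. Fibroblast identity genes rose in 6 and fell in 5 of 20 cases (adjusted p = 0.89; median 0.02, with a test that pointed down). Gelsolin, Gsn, rose from 3250 ± 61.4 to 15900 ± 2200 CPM and fibronectin, Fn1, fell from 3470 ± 60 to 803 ± 58.2 CPM. Universal and adventitial fibroblast genes rose in 4 and fell in 3 of 15 cases (adjusted p = 0.34), with Ly6a at 3.24 ± 0.21 and Igfbp6 at 2.57 ± 0.14. Adjusted over the list alone, 7 rose and 3 fell. Valve and tendon-like genes rose in 7 and fell in 5 of 15 cases (adjusted p = 0.4), and the test of that list pointed up while its median was -0.22. Of 17 smooth muscle and myofibroblast genes Synpo2 was among 2 that rose and Actg2 among 2 that fell (adjusted p = 0.34). Without Tcf21 P30 replicate 1 the smooth muscle list was called lower (adjusted p = 0.00071) and the universal fibroblast list higher (adjusted p = 0.05, just under the threshold before rounding).

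Interferon, complement, chemokine and hormone-responsive lists were higher at P30 by camera with the preset correlation. Of 23 interferon response and antigen presentation genes 19 rose, and 22 when adjusted over the list alone (adjusted p = 1.2e-20; adjusted p = 0.26 with an estimated correlation). Oasl2 rose from 9.88 ± 0.0657 CPM to 104 ± 7.6 CPM, and other risen genes were Usp18 (3.20 ± 0.32) and Rtp4 (2.91 ± 0.19). Of 11 complement genes 8 rose and 1 fell (adjusted p = 6.6e-12; adjusted p = 0.16 with an estimated correlation), with C1s1 at 2.58 ± 0.16 and C1ra at 2.57 ± 0.22. Of 19 chemokine and cytokine genes 13 rose (adjusted p = 3e-12; adjusted p = 0.087 with an estimated correlation), including Tnfsf13b (6.24 ± 0.42). Of 17 retinoid and glucocorticoid responsive genes 11 rose and 1 fell (adjusted p = 3.6e-08; adjusted p = 0.12 with an estimated correlation). The glucocorticoid-induced Zbtb16 was measured at 1.43 ± 0.501 CPM at P7 and 42.5 ± 3.14 CPM at P30 (4.88 ± 0.37), and the metallothionein genes Mt2 (3.52 ± 0.32) and Mt1 (2.55 ± 0.19) rose too. Of 16 lipid genes 6 rose and 2 fell (adjusted p = 0.003; adjusted p = 0.16 with an estimated correlation), such as Scd1 (1.84 ± 0.11) and Lpl (1.12 ± 0.13). Immediate early and dissociation stress genes rose in 13 of 22 cases (adjusted p = 4e-06; adjusted p = 0.42 with an estimated correlation), with Hspa1a at 2.30 ± 0.16. They rose in 3 cases with the Tcf21 P7 libraries summed.

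Of 25 neurotrophic and axon guidance ligands 6 rose and 5 fell (adjusted p = 0.087). The heparin-binding growth factor genes Ptn and Mdk, which act on neurite outgrowth, fell from 537 ± 16.8 to 41.6 ± 7.16 CPM (-3.69 ± 0.15) and from 287 ± 1.53 to 34.0 ± 5.24 CPM (-3.08 ± 0.13). Ntn4 rose (2.06 ± 0.13), as did the neurotrophin gene Ntf3 (1.69 ± 0.38), whose call was lost without Tcf21 P7 replicate 1 (adjusted p = 0.082) or 2 (adjusted p = 0.086). Without Tcf21 P7 replicate 1 or 2 this list was called lower (adjusted p = 0.038 and 0.046), and without replicate 2 so was the IGF list (adjusted p = 0.046). Of 25 secreted growth factors 6 rose, such as Fgf7 (1.87 ± 0.25), and Gdf10 was the 1 that fell (-2.06 ± 0.09; list adjusted p = 0.51). Of 22 TGF-beta and BMP genes 7 rose, such as Tgfbr3 (1.44 ± 0.11), and 2 fell (list adjusted p = 0.15). Of 25 Wnt genes 5 rose, such as Wnt11 (2.47 ± 0.21), and 9 fell, such as Sfrp2 (-1.74 ± 0.19; list adjusted p = 0.2).

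Transcripts of other cell types were lower at P30 for several lists. Macrophage genes fell in 11 of 17 cases (adjusted p = 7.6e-10; adjusted p = 0.3 with an estimated correlation), such as Adgre1 (-1.89 ± 0.21). Cardiomyocyte genes fell in 7 of 20 cases (camera adjusted p = 0.00014, or 0.46 with an estimated correlation), led by Tnni1 and Myl7 (-2.26 ± 0.28). Summed over the list they amounted to 2280 and 2090 CPM in Tcf21 P7. The sums at P30 were 2060 CPM in replicate 1, near the P7 level, and 1280 and 1370 CPM in replicates 2 and 3. Epicardial genes fell in 3 of 11 cases (adjusted p = 0.00035; adjusted p = 0.3 with an estimated correlation), with Aldh1a2, a retinoic acid synthesis gene, at 626 ± 0.805 CPM at P7 and 134 ± 15 CPM at P30. Of 10 Schwann cell and glia genes Cdh19 (1.91 ± 0.17) was among 2 that rose and Ncam1 (-1.26 ± 0.14) fell (list adjusted p = 0.35). Of 8 erythroid genes Slc4a1 fell and of 12 pericyte genes Pdgfrb rose (list adjusted p = 0.4 and 0.93), and neither call held with the Tcf21 P7 libraries summed. Without both endothelial-rich libraries the pericyte list was called lower, among several lists called only there. No endothelial or lymphocyte gene was called (list adjusted p = 0.44 and 0.89). Endothelial transcripts summed to 5050 CPM in Tcf21 P30 replicate 1 against 1440 and 1710 CPM in the other libraries of that group.

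Provisional gene models, transcripts for which the annotation still lacks experimental evidence, moved with both comparisons. Their share of counts was 0.23% in each Tcf21 P7 library (95% Wilson interval 0.228 to 0.232), 0.368% in each Postn P7 library (0.365 to 0.371) and 0.354% to 0.366% in the Tcf21 P30 libraries (bounds of 0.351 to 0.369). The intervals cover counting error alone. Of the 611 models tested 134 were higher and 3 lower in Postn P7 than in Tcf21 P7, and 197 were higher and 18 lower at P30. The nuclear RNA Malat1, named after its values were seen, was measured at 1160 and 1370 CPM in the Postn P7 libraries, 354 and 341 CPM in the Tcf21 P7 libraries and 1410 to 1560 CPM in the Tcf21 P30 libraries.

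**Figure D4:**
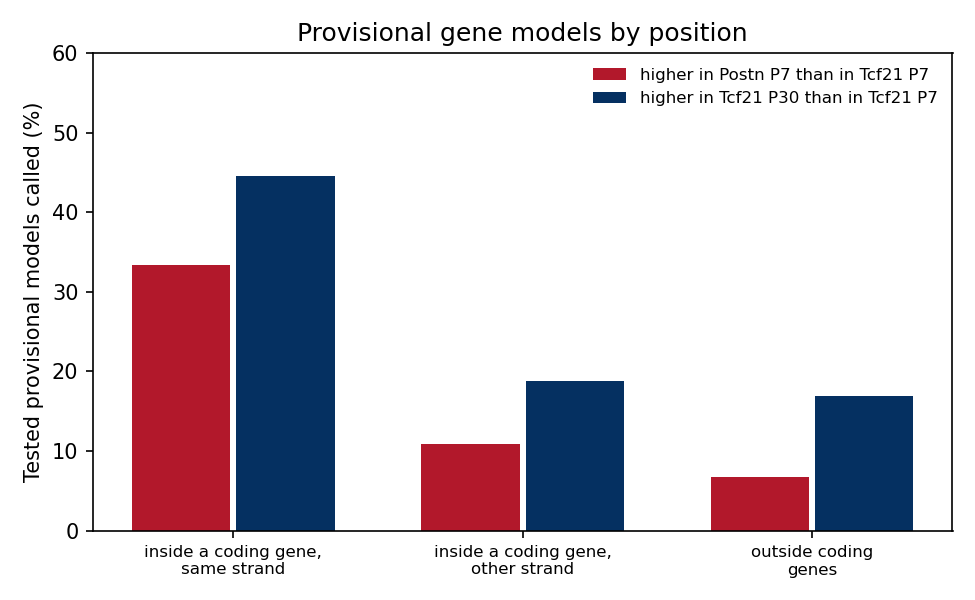
Percentage of tested provisional gene models called higher in Postn P7 (red) and in Tcf21 P30 (blue) than in Tcf21 P7, for models inside a coding gene on the same strand (332), inside on the other strand (101) and outside coding genes (178). Of the models inside on the same strand 33.4% were higher in Postn P7 and 44.6% at P30, against 6.74% and 16.9% of those outside.

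**Figure D5:**
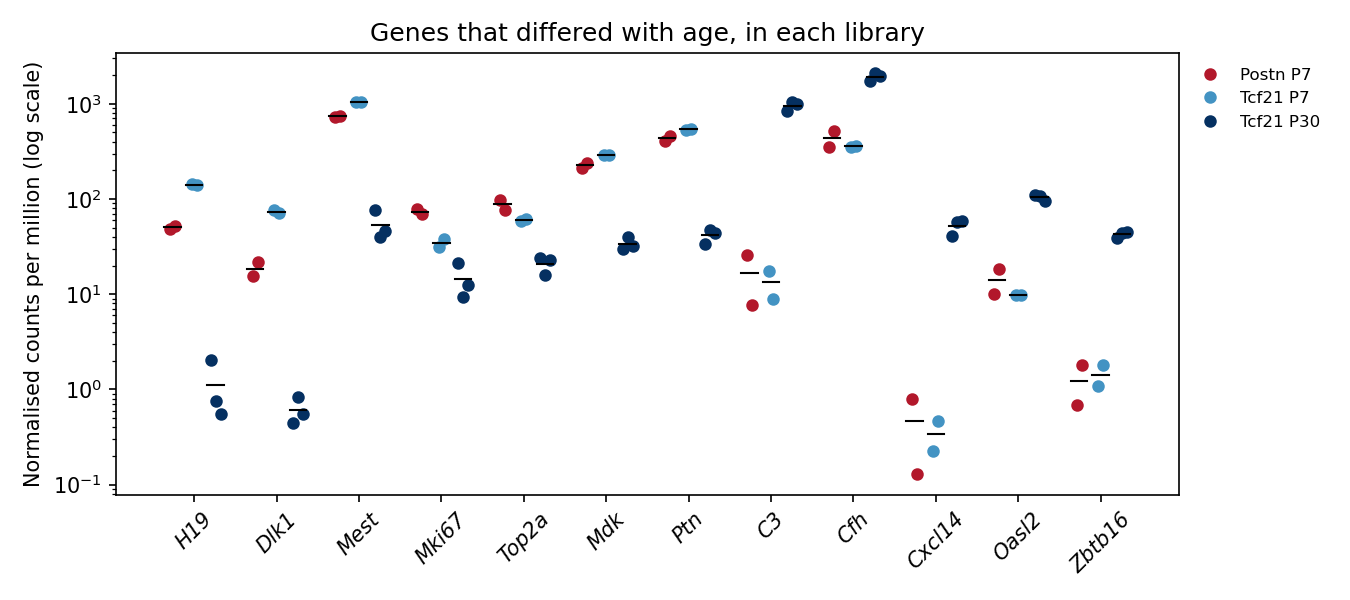
Normalised CPM (log axis) of 12 genes that differed with age, with a point per library and a line at the mean of each group. H19, Dlk1, Mdk and Ptn were lower in every Tcf21 P30 library than in every P7 library, C3, Cxcl14, Oasl2 and Zbtb16 were higher, and Mki67 and Top2a averaged 14.4 ± 6.31 and 21.0 ± 4.54 CPM (SD, n = 3) at P30.

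The calls of lineage and age were then set side by side. Of the 1149 genes higher in Postn P7 than in Tcf21 P7, 758 were also higher at P30, 64 were lower and 327 were not called with age. Of the 969 genes lower in Postn P7, 494 were also lower at P30, 111 were higher and 364 were not called. For independent lists 192 genes would be higher in both and 146 lower in both, a number that does not allow for the shared controls. The covariance of the fold changes across genes was 0.6, against 0.09 to 0.11 in 50 simulated data sets without any change that shared the same controls. Those data sets hold noise alone, and a real difference of Tcf21 P7 from both other groups would also raise the covariance. Its excess therefore does not show a response shared by lineage and age. The correlation was 0.57 against a simulated mean of 0.55. In data sets of noise alone a shared control by itself sets a correlation of this size. The comparison of correlations therefore cannot decide how much of the observed correlation comes from the shared controls. Because both comparisons use the 2 Tcf21 P7 libraries, part of the excess of shared calls may come from those libraries. With replicate 1 as the control for lineage and replicate 2 for age, a split chosen after the data were seen, 45 genes were higher and 12 lower in both, against 3.11 and 1.45 for independent lists. With the controls exchanged 47 were higher and 10 lower, and the correlation was 0.43 in each split. The covariance was 0.76 in each split, over 18749 genes. A difference that both Tcf21 P7 libraries have in common is not removed by the split. The 1252 genes called in the same direction numbered 92 or 88 without replicate 1 or 2 of Tcf21 P7 and 95 with the Tcf21 P7 libraries summed. They numbered 726 or 351 without replicate 1 or 2 of Postn P7 and 618 without Tcf21 P30 replicate 3. Of the 758 genes higher in both, 516 were protein coding and 116 were provisional models, and of the 494 lower in both, 459 were protein coding and 2 were provisional models. Dnm3os, Kcnq1ot1, Firre and Enpep were among the named genes higher in both, and Dlk1, H19, C1qa and Adgre1 among those lower in both. Pi16 and Efemp1 were lower in Postn P7 and higher at P30, and Wisp1 and the mitosis genes Cenpe, Cenpf, Kif11 and Hmmr were higher in Postn P7 and lower at P30.

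The comparison of Postn P7 with Tcf21 P30 changed lineage and age together, and its fold changes equal the difference of those above. Most mitosis, DNA replication and imprinted growth genes were higher in Postn P7, and most interferon and complement genes were lower. Col24a1 was measured at 42.7 ± 3.41 CPM (SD, n = 2) in Postn P7 and 0.742 ± 0.0996 CPM (SD, n = 3) in Tcf21 P30 (5.83 ± 0.17). Tnni1 was higher by 7.07 ± 0.43, H19 by 5.52 ± 0.38, Plppr5 by 5.31 ± 0.25, Dlk1 by 4.92 ± 0.24, Cthrc1 by 4.89 ± 0.16 and the carbonic anhydrase gene Car3 by 4.79 ± 0.28. Clca3a1, Zim1 and the antisense RNA Nespas were also among the largest increases (5.91 ± 0.51, 5.20 ± 0.52 and 4.93 ± 0.31), with uncertain assignment of reads as for the genes above. The largest decreases were Ifi205 (-7.33 ± 0.54), Mmp3 (-7.22 ± 0.30), Inmt (-7.13 ± 0.68), Cxcl14 (-6.73 ± 0.52), Ces1d (-6.73 ± 0.34), Ppl (-6.39 ± 0.25), Gsta3 (-6.23 ± 0.30), Esr1 (-5.94 ± 0.21), C3 (-5.83 ± 0.67) and Hsd11b1 (-5.63 ± 0.33). Ces1d, Ifi205 and Gsta3 have close paralogs.

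In this comparison 4276 genes (24.2%) were called, 2070 higher and 2206 lower in Postn P7. With library size alone as the scaling, which moved the median by 0.106, 2802 were higher and 1725 lower. Without Postn P7 replicate 1, 2810 genes were called. Camera called 7 lists higher and 9 lower with the preset correlation and none with an estimated correlation, whose smallest adjusted p was 0.051, for mitosis and for imprinted growth genes. Of 24 mitosis genes 23 were higher (adjusted p = 1.8e-42) and of 15 imprinted genes 10 were higher and 1 lower (adjusted p = 2.5e-16). Of 24 DNA replication genes 21 were higher (adjusted p = 8.5e-14; adjusted p = 0.19 with an estimated correlation). Of 23 interferon genes 19 were lower (adjusted p = 1.4e-21; adjusted p = 0.24 with an estimated correlation). Complement genes were lower in 8 and higher in 1 of 11 cases (adjusted p = 6.4e-12; adjusted p = 0.17 with an estimated correlation). Chemokine and cytokine genes were lower in 10 of 19 cases (adjusted p = 2.9e-09; adjusted p = 0.094 with an estimated correlation). Retinoid and glucocorticoid responsive genes were lower in 11 and higher in 1 of 17 cases, and lipid genes lower in 7 and higher in 1 of 16 (adjusted p = 6e-11 and 2.3e-06; adjusted p = 0.062 with an estimated correlation for each). Of 15 universal and adventitial fibroblast genes 8 were lower and 3 higher (adjusted p = 2.3e-07; adjusted p = 0.3 with an estimated correlation), with Pi16 at -2.33 ± 0.11 and Ly6a at -3.88 ± 0.22. Ptn (3.38 ± 0.15), Mdk (2.73 ± 0.13) and Gdf10 (2.69 ± 0.09) were higher in Postn P7, as was Lef1 (3.09 ± 0.40), a transcription factor of Wnt signalling. Of 17 macrophage genes Cd14 (-1.08 ± 0.23) and C1qa (-0.61 ± 0.17) were lower and the list was not called (adjusted p = 0.99). Matricellular genes were higher as a list (adjusted p = 0.0051; adjusted p = 0.5 with an estimated correlation), as were smooth muscle (0.045; 0.74), epicardial (0.0075; 0.5) and cardiomyocyte genes (0.016; 0.74). Fibroblast identity genes were lower (0.045; 0.74), as were valve (0.023; 0.3) and immediate early genes (0.014; 0.74), although the valve list had a median of 0.08. Each of these 7 calls was lost without some single libraries. Without Postn P7 replicate 1 the adjusted p was 0.17 for smooth muscle, 0.17 for epicardial, 0.55 for cardiomyocyte, 0.2 for fibroblast identity and 0.51 for immediate early genes. For matricellular and valve genes it was 0.1 and 0.12 without Postn P7 replicate 2. Without Tcf21 P30 replicate 2 it was 0.097 for fibroblast identity, 0.087 for smooth muscle and 0.06 for valve genes, and without Tcf21 P30 replicate 3 it was 0.071 for fibroblast identity and 0.099 for smooth muscle genes.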

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

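The settings with summed Tcf21 P7 libraries, with protein-coding genes alone and without both endothelial-rich libraries were chosen after the data were seen. Of 6526 values of named genes under alternatives, 5794 kept direction and side of the threshold, 725 kept direction but no longer passed, 7 passed only there and none reversed. Most named genes were chosen as called in the reported fit, and the largest changes also for no overlap between libraries. Reversals were therefore unlikely from the outset. The total pools settings close to the reported fit with settings that leave out or sum libraries. The calls of Postn and Tcf21 were the same in all 118 of their values. Of 1120 values of lists, 984 were the same, 92 no longer passed, 43 passed only there and 1 reversed. That was the pericyte list with age, called lower (adjusted p = 0.021) with both endothelial-rich libraries left out, and the cause was not tested.

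Counts are given for Postn P7 against Tcf21 P7, for age, and for Postn P7 against Tcf21 P30. Genes passing the threshold and a 2-fold change numbered 767, 2544 and 1951, and those passing a test against a 2-fold change 32, 877 and 804. Leaving out a library gave 111 to 1106, 2418 to 6063 and 2810 to 5072 genes, where a lone library is assumed to vary like the other groups. With the Tcf21 P7 libraries summed, 123 and 2463 genes were called in the first comparisons. The first count was 3442 with no filter beyond 1 count and 3750 without both endothelial-rich libraries. With a block for replicate number the counts were 1556, 4553 and 3348. Lists called with an estimated correlation numbered 0, 1 and 0, and fry called 4, 18 and 12. Genes called in the same direction with lineage and age numbered 442 with a 2-fold minimum, 88 to 1669 with a library left out and 95 with summed libraries. Leaving out or summing libraries reduces power by construction, but some counts rose there, and the cause of these rises and of the other changes was not tested.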

Other observations

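Of the tests below, those of the recombinase cassettes, of genomic DNA and of a lower share of fibroblasts, the lists of ribosomal, oxidative phosphorylation, lysosomal, cardiogenic, integrin and Notch genes, and the rule that picks genes by lineage and not by age were chosen only after the result was seen. The intervals set against the bounds of the tests of chromosome 10 and of genomic DNA were also added after the values were seen.

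Some genes were called in the same direction against both Tcf21 groups and not called with age, which does not show that they did not change with age (Carmn, among them, had 1.09 with age at an adjusted p of 0.069). Of these, 189 were higher in Postn P7, 164 of them protein coding, and 226 were lower, 217 of them protein coding. Of the 415, 13 or 12 kept their call against Tcf21 P7 without replicate 1 or 2 of that group and 13 with its libraries summed. All 415 kept their direction there, with a median absolute change of 0.66 to 0.67 against 0.67 in the reported fit. Their median standard error was 0.18 against 0.13. The genes had been chosen as called in a fit with these libraries, and summing hardly moves a group mean. Kept direction and size therefore give no support to the changes. Nr2f2, Ret, Angptl7, Ackr4 and Esr1 kept their call in each of these Tcf21 P7 settings, and the other genes named here lost theirs. Without Tcf21 P30 replicate 3, 192 of the 415 kept their call against Tcf21 P7, and Hey2 was among those that lost it. Calls were also lost when either Postn P7 library was left out. Both comparisons share the Postn P7 libraries, and agreement between them was not set against unchanged data. The genes named here were chosen after their values were seen, and levels are means with n = 2, 2 and 3. The transcription factor gene Nr2f2 stood at 58.9 CPM in Postn P7, 23.9 CPM in Tcf21 P7 and 26.2 CPM in Tcf21 P30 (1.30 ± 0.13 against Tcf21 P7, adjusted p = 0.0029). The glutamate receptor gene Gria3 was higher by 1.10 ± 0.13, the renal stroma factor Foxd1 by 1.75 ± 0.33 and the Notch target Hey2 by 1.45 ± 0.38. Among the lower genes, Ret, a receptor of GDNF-family neurotrophic factors, stood at 60.5, 217 and 285 CPM (-1.85 ± 0.16, adjusted p = 0.0017). The protease gene Pcsk6 stood at 908, 2190 and 2050 CPM, the secreted Angptl7 changed by -1.80 ± 0.20 and the chemokine scavenger gene Ackr4 by -1.24 ± 0.12.

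Ribosomal protein genes were lower than in Tcf21 P7 in both other groups, 16 of 24 in Postn P7 (median -0.54, adjusted p = 2.3e-11; 0.5 with an estimated correlation) and 22 of 24 at P30 (median -0.47, adjusted p = 7.2e-05; 0.53 with an estimated correlation). Rplp0 stood at 280, 430 and 330 CPM. With library size alone as the scaling 4 and 15 were lower, and with the Tcf21 P7 libraries summed 0 and 2. Of 25 nuclear-encoded oxidative phosphorylation genes 9 were lower in Postn P7 than in Tcf21 P7 (adjusted p = 5.5e-07; 0.28 with an estimated correlation), 13 were lower and 1 higher at P30 than in Tcf21 P7 (adjusted p = 0.01; 0.53), and 1 was lower in Postn P7 than in Tcf21 P30. The first count was 4 with upper-quartile factors, 1 (and 1 higher) with library size alone and 0 with the Tcf21 P7 libraries summed, where 1 was lower at P30. Of 20 lysosomal genes 12 were lower and 1 higher in Postn P7 than in Tcf21 P30 (adjusted p = 0.00034; 0.83 with an estimated correlation), with Ctsh at -1.58 ± 0.10. Of 15 cardiogenic transcription factors 4 fell with age (2 with the Tcf21 P7 libraries summed), among them Tbx20 (-1.30 ± 0.17) and Gata4 (-0.83 ± 0.15). No integrin gene of 19 was called between the lineages at P7. Of 17 Notch genes Hey2 and Heyl (0.49 ± 0.13) were higher and Hes1 was lower (-0.44 ± 0.10), and the list was not called (adjusted p = 0.69). No Notch gene was lower with upper-quartile factors or library size alone, and none was called with the Tcf21 P7 libraries summed.

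Esr1 was near absent in Postn P7 and abundant in both Tcf21 groups. Transcripts of a cassette that each driver expresses in its own line were argued against, since Esr1 stood at no more than 0.00122 of the Postn level in a Postn P7 library, against 0.489 to 0.597 of the Tcf21 level in the Tcf21 libraries. A cassette read from the Tcf21 allele alone may account for it and cannot be told apart from a lineage difference, because the Esr1 to Tcf21 ratio varied 1.22-fold where Tcf21 itself varied 1.45-fold. Strain sequence carried along chromosome 10 also stays open, since 14.6% of the 89 tested genes between both loci were called (95% Wilson interval 8.74 to 23.4, past the 18% set for that test), against 12% elsewhere (Fisher's exact test, p = 0.41). A lineage difference in Esr1 itself was not tested.

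Provisional gene models were higher in Postn P7 and Tcf21 P30 than in Tcf21 P7. Low counts alone were argued against by a median 1.32 above that of coding genes of the same expression (95% interval 1.1 to 1.48). That interval came from resampling the models. Like the Fisher test over models below, it does not cover the spread between libraries. More unspliced transcript of the host genes may account for the pattern, since 28.2% of models inside coding genes were higher in Postn P7, against 6.74% outside (Fisher's exact test, p = 4.4e-10), and 33.4% of those on the host's strand, against 10.9% on the other. The first test of genomic DNA set the share of provisional models against counts of olfactory and vomeronasal genes within Tcf21 P30 and left it open, since the highest library there had 1.02 times the counts of the next. The test by position of the models was put in its place after that result was seen. Across the groups the olfactory and vomeronasal genes went with genomic DNA, at 68 and 59 CPM in Postn P7, 31.6 and 32.9 CPM in Tcf21 P7 and 55.3 to 98 CPM in Tcf21 P30. Within Tcf21 P30 they went both ways, at 95.9, 55.3 and 98 CPM in replicates 1, 2 and 3 beside provisional-model shares of 0.366%, 0.354% and 0.354%, and 451 of them had a count in replicate 3 against 89 and 56 in the others. By position, the 6.74% outside (95% Wilson interval 3.9 to 11.4) reached past the bound of 11.1%, and at P30 16.9% outside lay above the bound of 14.9%. The median log2 fold change in Postn P7 was 2.5 on the host's strand, 0.22 on the other strand and 0.28 outside. At P30 it was 2.48, 0.32 and 0.27. A source that raises models alike at every position would not give this by itself. Genomic DNA as part of the pattern cannot be told apart from unspliced transcript, since the olfactory and vomeronasal genes went with it across the groups. Whether such a difference comes from handling of the Tcf21 P7 libraries or from the cells was not tested.

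Macrophage transcripts were higher in Tcf21 P7 than in the other groups. Macrophages carried through the sort may be a source, since 22 further macrophage transcripts had a median of -1.36 in Postn P7 against Tcf21 P7, with 21 below 0 and 12 called lower. The most abundant of them in Tcf21 P7, F13a1, stood at 53.4, 166 and 72.3 CPM in Postn P7, Tcf21 P7 and Tcf21 P30, and Irf8 at 94.7, 131 and 55.1 CPM. A lower share of fibroblasts in Tcf21 P7 was not decided. All 3 of the endothelial, pericyte and Schwann cell lists had medians at or above 0 in Postn P7 (0.34, 1.18 and 1.82), with Pdgfrb called higher there. Such lists may also differ by what each driver gene traces. Endothelial transcripts summed to 2260 and 1420 CPM in Postn P7 against 1680 and 1500 CPM in Tcf21 P7. Fibroblast identity transcripts were not lower in Tcf21 P7, at 65600 CPM in each library against 48000 and 58100 CPM in Postn P7. The erythroid (-1.19) and cardiomyocyte (-0.39) medians lay on the macrophage side, but neither these lists nor the endothelial list had a called member. Camera with the preset correlation called the erythroid list lower (adjusted p = 0.045) and did not call the endothelial list (adjusted p = 0.86). The myeloid granule genes Ngp, Ltf and Camp, named after their values were seen, ran opposite to the macrophage genes. Ngp stood at 6.72 and 10.4 CPM in Postn P7 and at 0.114 and 0.115 CPM in Tcf21 P7, Ltf at 4.12 and 15.7 against 0.114 and 0 CPM, and Camp at 1.64 and 2.82 against 0 CPM. The sort for the reporter would remove macrophages that do not carry it, and macrophage genes expressed by the traced cells themselves were not tested for.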
